A study of Mus musculus with 4 samples.

How the data were processed

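RNA of mouse bone marrow dendritic cells (DC) of the C57BL/6 strain was measured on 4 Affymetrix mouse expression arrays, 2 of immature DC and 2 of DC modulated by natural killer T (NKT) cells, per the labels. The design text states that RNA came from CD11c cells. It names a labelling kit with a single amplification cycle, whereas the sample labels name an assay with a pair of cycles, so the amplification used is not settled here. The design text also speaks of triplicates and of a repeat of the experiment; 2 arrays per group were analysed here, and nothing says whether they came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical.

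The deposited values are linear intensities, 1 signal per probe set and array, in a table of 22690 rows. The design text names an array type that carries more probe sets than that, so the table may hold part of its probe sets or come from another array of the family. Members of a list that were not measured here are therefore not read as absent from the cells or from the array. The authors scanned the arrays and analysed the images with GCOS, the Affymetrix operating software, per the submitters' processing notes; its version, the summary algorithm and the scaling target are not given in the sources used here. The design text describes log transformation and removal of intensity-dependent bias, but the deposited intensities are on a linear scale. The 2% trimmed mean of an array ranged from 585.3 to 655.8, a spread of 12.1%, so the arrays did not share 1 scaling target over all probe sets. No detection calls were used, and the small number of arrays limits the precision.

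Before the data were examined, the groups, the tests, 37 gene lists, the rule for naming genes and most alternatives were fixed. The rule for normalization required quantile normalization if the quartiles of the arrays differed by over 0.1 on the log2 scale; they differed by 0.271. Signals were turned into log2(signal + 16) and quantile normalized. A fold change on this scale understates the change of genes with signals near or below the pseudocount of 16. The 64 control probe sets were left out, and 22626 probe sets were tested without a filter on dim ones.

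Probe sets were named through a table of the platform's annotation. Of those tested, 20380 had 1 gene symbol, 691 had several, and 1555 were unnamed here. Symbols of 20351 probe sets were updated by gene ID through a RefSeq gene table of the GRCm38.p6 assembly, used for names only. Each of the 12393 genes was represented by its brightest probe set. Of 868 called genes with several probe sets, 0 had another probe set called in the opposite direction, and 183 genes were called by another probe set but not by the brightest. Other probe sets of a called gene need not pass. For Mycl 1 of 3 was called, and for Lif and Irf4 1 of 2, whereas for Cflar 4 of 4 were called.

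Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A limma fit of these arrays had 2 residual degrees of freedom and 4.13 prior degrees of freedom. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists, with an estimated correlation and fry as alternatives. Within a list, calls were counted after adjustment over all genes and adjusted over the list alone. The genes named are the 12 largest rises and the 12 largest falls among called genes whose arrays did not overlap between groups, up to 4 members of each list with the smallest p (up to 2 where no member was called), and 14 genes fixed in advance as readouts. The non-overlap part of the rule removed 0 called genes, since it held for 100% of them. Passing the threshold selects for such separation, so this share is no evidence beyond the calls. Chance gives 33.3% for unselected genes in groups of this size. Genes with only a clone or predicted-gene name were passed over among the largest changes. Genes named outside this rule are said to be.

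The limma steps were tested on simulated data, for the comparison of NKT-modulated with immature DC over 22626 probe sets. Means were the real ones. The spread was drawn around the real trend of SD with signal, using the prior degrees of freedom that limma had fitted. The noise thus follows the model that limma assumes, so the share of false calls checks the steps and not that model. In 5 runs with 200 changed probe sets each, 493 calls were made, of which 18 (3.65%) were false. Recovery was 3.2% at the smallest simulated change, below a log2 change of 1, then 20.8% at a log2 change of 1, 72.4% at 2 and 93.6% at 3. The real comparison called 2501 probe sets, more than the 200 changed per run. The adjusted p depends on how many probe sets change, so recovery in the real data may differ. Of 185 tests of lists not selected for change, 0 were called. Changed probe sets were drawn at random, so some may lie in a list. Noise was drawn independently for each probe set, so these tests cannot tell how camera behaves when list members are correlated. Of the 64 real control probe sets, limma called 0 between the groups, with 9 at an unadjusted p under 0.05. Among those 9, the 5′ Gapdh probe set was lower in the NKT-modulated arrays (-0.215) and the rest were higher. The largest rise was 0.429, for a bioB control. A small offset between the groups in these controls is therefore not excluded.

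The alternatives were no further normalization, cyclic loess, leaving out probe sets below the lower quartile or below the median of mean signal, eBayes without the intensity trend, array weights, pseudocounts of 1 and 64, the mean over the probe sets of a gene, stricter thresholds and leaving out each array in turn. An alternative that left out genes known to be made by activated T cells, together with the T and NKT marker list, from every other list was added after the data were seen. The median log2 change of all genes was -0.04 after quantile normalization, -0.12 without further normalization and -0.01 after cyclic loess, and changes are to be read relative to it.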

Results

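Gene expression was measured in bone marrow dendritic cells (DC), antigen-presenting cells grown from mouse bone marrow, on 4 arrays. The 2 groups were immature DC and DC modulated by NKT cells, a T cell population that recognises lipids presented by CD1d, with 2 arrays each. Median log2(signal + 16) before normalization was 7.34 and 7.44 in the immature arrays and 7.24 and 7.18 in the NKT-modulated arrays. The Pearson correlation of log2 signals across probe sets was 0.987 and 0.985 within the groups and 0.961 to 0.966 between them. The SD of log2 differences between 2 arrays was 0.39 and 0.42 within groups and 0.64 to 0.68 between groups. No pair of arrays held identical values. The Gapdh 3′ to 5′ signal ratio was 1.76 and 1.44 in the immature arrays and 1.87 and 1.98 in the NKT-modulated arrays, and that of Actb lay between 1.09 and 1.18 in all 4.

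The comparison asked how RNA of the NKT-modulated DC samples differed from that of the immature DC samples. The steepest rises were in cytokine genes. Il5, Il13 and Il4, type 2 cytokines, rose by 8.94 ± 0.14, 8.36 ± 0.13 and 7.22 ± 0.18 on the log2 scale (SE, n = 2 arrays per group, as for all changes given here). Csf2, the gene of the growth factor GM-CSF, rose by 8.12 ± 0.14, and Ifng and Il17a, cytokines of other T cell subsets, rose by 7.0 ± 0.25 and 6.54 ± 0.20. Genes of interferon responses, inflammatory cytokines and costimulation also rose, while genes of the cell cycle and of cholesterol synthesis fell; each of these lists passed camera at the preset correlation and had adjusted p = 0.154 with an estimated correlation. T and NKT cell markers rose in the same arrays, 14 of 22 measured, so which cells made the T cell cytokine transcripts is not settled here. The fall was steepest for Rgs18, a regulator of G protein signalling, at -2.90 ± 0.17.

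Of 12393 genes, 824 were higher and 1001 lower in NKT-modulated DC at an adjusted p under 0.05. At the level of probe sets, 1212 were higher and 1289 lower of 22626, so that 48.5% of calls were higher; the share was 36.6% without further normalization and 56.2% after cyclic loess. Rises reached further than falls: 29 genes rose by more than 16-fold and 0 fell by that much. Changes of at least 2-fold numbered 408 higher and 301 lower genes. Without the intensity trend of the variance, 471 genes were higher and 396 lower, and at the threshold of 0.001 that the design text gives, applied to the adjusted p, 170 were higher and 47 lower. Leaving out immature replicate 1, immature replicate 2, NKT-modulated replicate 1 or NKT-modulated replicate 2 gave 597, 593, 494 and 539 genes higher and 499, 512, 446 and 560 lower, in that order.

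**Figure D1:**
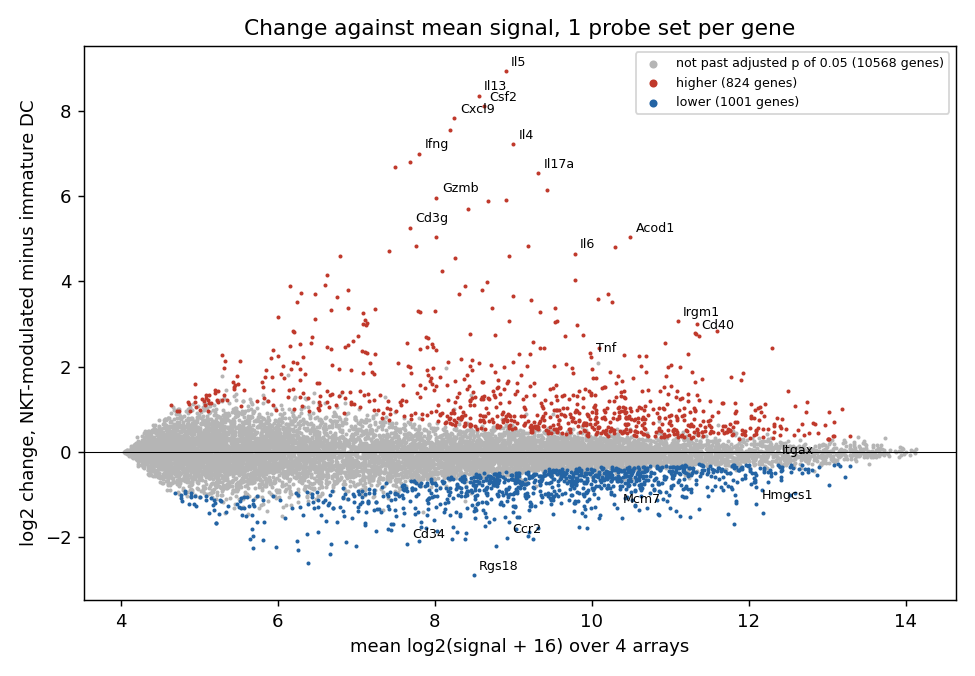
Log2 change of each gene (NKT-modulated minus immature DC, vertical axis) against its mean log2(signal + 16) over 4 arrays (horizontal axis); each point is 1 gene, red for the 824 called higher, blue for the 1001 called lower and grey for the rest. Rises extended to 8.94 for Il5, and falls to -2.90 for Rgs18.

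Cytokine genes filled most of the places among the 12 largest rises. Besides those above, Il3 rose by 6.69 ± 0.22, and the chemokine genes Cxcl9 and Ccl1 rose by 7.83 ± 0.15 and 6.15 ± 0.22. Gzmb, encoding the protease granzyme B of cytotoxic lymphocytes, rose by 5.97 ± 0.30. Cyp11a1, the enzyme that starts steroid hormone synthesis, rose by 6.81 ± 0.19, and Ctla2a, a cysteine protease inhibitor with a near-identical paralog that its probe set may not separate, rose by 7.56 ± 0.17. The adjusted p of these 12 genes lay between 1.89e-06 and 8.94e-05. Signals of Il5 were 7.83 and 3.54 in the immature arrays and 11670 and 10170 in the NKT-modulated arrays; those of Il4 were 30.1 and 22.1 against 7559 and 5281. Where immature signals lay below the pseudocount of 16, as for Il5, the size of the change, and with it the rank among the rises, depends on that choice.

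T lineage transcripts rose in the same arrays. Of 22 measured genes of the T and NKT cell marker list, 14 rose and 0 fell, with a median log2 change of 2.22; the counts adjusted over the list alone were 14 and 0. Cd3g, a chain of the CD3 complex of the T cell receptor, rose by 5.26 ± 0.20 (adjusted p = 3.80e-05), from signals of 19.1 and 15.4 to 1401 and 1046. Gata3, a transcription factor of T cell development and of type 2 T cells, rose by 4.72 ± 0.19, and Il4 and Ifng belong to this list too. Camera gave adjusted p = 1.42e-14 for the list, and adjusted p = 0.154 with an estimated correlation. The design text states that the RNA came from CD11c cells, CD11c being the DC integrin encoded by Itgax. Of 11 NK cell markers, 5 rose, among them Il2rb by 4.14 ± 0.23 and Xcl1 by 3.63 ± 0.31, while Klrd1, the NK receptor chain CD94, fell by 1.91 ± 0.16; adjusted over the list alone, 5 were higher and 1 lower. The NK list had adjusted p = 3.06e-04, and adjusted p = 0.288 with an estimated correlation; without genes known to be made by activated T cells, 2 of 8 were higher (adjusted p = 0.135).

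**Figure D2:**
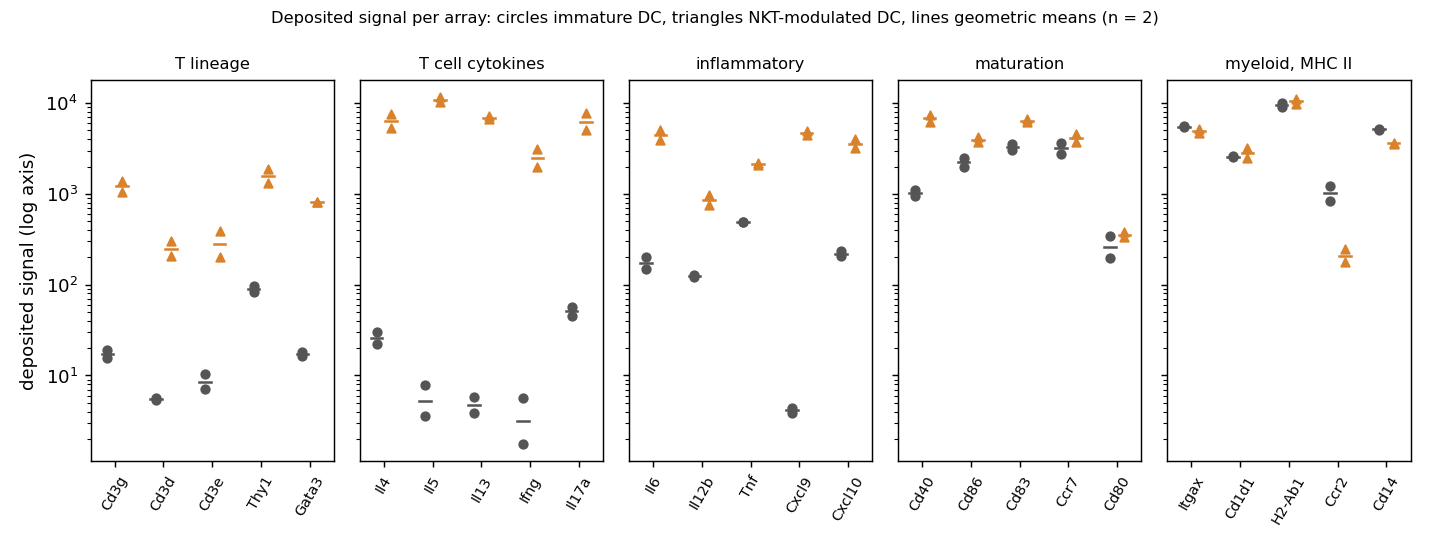
Deposited signal of 25 genes per array on a log axis, in 5 panels of 5 genes; circles are the 2 immature DC arrays, triangles the 2 NKT-modulated DC arrays and short lines their geometric means. Cd3g signals were 19.1 and 15.4 in immature arrays and 1401 and 1046 in NKT-modulated arrays, whereas Itgax signals were 5442 and 5537 against 5253 and 4643.

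Inflammatory cytokine genes rose together. Of 17 measured, 13 rose and 2 fell, with a median change of 2.22, and the counts adjusted over the list alone were 13 and 2. Il6 rose by 4.65 ± 0.14, Tnfsf11, the gene of RANK ligand, by 5.05 ± 0.17 and Lif by 4.56 ± 0.20. For inflammatory cytokines camera gave adjusted p = 2.47e-11, and adjusted p = 0.154 with an estimated correlation. The T lineage transcripts moved with this list; without genes known to be made by activated T cells, such as Csf2, Lif and Tnfsf11, 8 of 11 members rose and 1 fell (adjusted p = 3.06e-07). Of 19 chemokine genes, 11 rose and 0 fell, also when adjusted over the list alone. Cxcl10, a ligand of CXCR3, rose by 4.04 ± 0.12, Ccl24, an eosinophil attractant, by 3.67 ± 0.14 and Ccl4 by 2.28 ± 0.10. The chemokine list had adjusted p = 8.07e-08, and adjusted p = 0.154 with an estimated correlation; without genes of activated T cells, 9 of 15 rose.

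Interferon response genes were higher in NKT-modulated DC, beside the rise of Ifng itself. Of 22 interferon gamma response genes, 17 rose and 1 fell, with a median change of 2.31. Acod1, the enzyme that makes itaconate, rose by 5.04 ± 0.12, and the interferon-inducible GTPase genes Iigp1 and Irgm1 rose by 4.61 ± 0.12 and 3.07 ± 0.10. Of 25 type I interferon response genes, 20 rose and 0 fell, with a median of 1.13, among them Ifi204 by 2.72 ± 0.12, Ifit2 by 2.30 ± 0.15 and Ifih1, a sensor of viral RNA, by 1.53 ± 0.09. Adjusted over the list alone, 18 rose and 1 fell in the first list and 22 rose and 0 fell in the other. Each list had adjusted p = 4.61e-16, and adjusted p = 0.154 with an estimated correlation. Without genes of activated T cells, 15 of 20 interferon gamma response genes rose, and the type I list lost no member.

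Genes of antigen presentation on MHC class I rose in part. Of 15 measured, 6 rose and 0 fell, and 7 were higher when adjusted over the list alone. Psmb10, an immunoproteasome subunit, rose by 0.72 ± 0.08, and Erap1, the peptide-trimming aminopeptidase, by 0.88 ± 0.11. The MHC class I list had adjusted p = 4.61e-04, and adjusted p = 0.154 with an estimated correlation. It held 0 genes of the activated T cell set.

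IL-4 and IL-13 response genes went both ways, with more rises than falls. Of 23 genes, 11 rose and 3 fell; adjusted over the list alone, 14 were higher and 4 lower. Irf4, a transcription factor of DC and lymphocytes, rose by 1.14 ± 0.08, Pdcd1lg2, the gene of the PD-1 ligand PD-L2, by 1.26 ± 0.09 and Tgm2, a transglutaminase, by 1.02 ± 0.08. This response had adjusted p = 1.66e-04, and adjusted p = 0.206 with an estimated correlation; without genes of activated T cells, 6 of 16 rose and 2 fell (adjusted p = 0.0122). Of 22 JAK-STAT and SOCS genes, 12 rose and 2 fell, and 14 and 3 when adjusted over the list alone. Stat5a rose by 1.88 ± 0.12, and the cytokine signalling inhibitors Socs1 and Socs3 by 1.96 ± 0.18 and 1.86 ± 0.08. This list had adjusted p = 1.31e-04, and adjusted p = 0.154 with an estimated correlation; without genes of activated T cells, 7 of 16 rose and 2 fell (adjusted p = 0.0569).

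Maturation and costimulation genes were higher. Of 25 measured, 18 rose and 0 fell, with a median change of 0.94, and 21 were higher when adjusted over the list alone. Cd40, the costimulatory receptor, rose by 2.76 ± 0.09 (adjusted p = 1.67e-05), from signals of 947.3 and 1091 to 7419 and 6258. Cd200 rose by 1.52 ± 0.10, Icam1, an adhesion molecule, by 1.08 ± 0.07 and Cd274, the gene of PD-L1, by 1.06 ± 0.08. The list had adjusted p = 3.04e-14, and adjusted p = 0.154 with an estimated correlation; without genes of activated T cells, 7 of 13 rose and 0 fell. Of 22 NF-kB pathway genes, 18 rose and 0 fell, and 19 were higher when adjusted over the list alone. Cflar, an inhibitor of caspase-8 activation, rose by 1.77 ± 0.08, Tnfaip2 by 1.44 ± 0.08 and Traf1 by 1.25 ± 0.10. The NF-kB list had adjusted p = 6.15e-12, and adjusted p = 0.154 with an estimated correlation; without genes of activated T cells, 13 of 17 rose.

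The readouts fixed in advance split by gene. Cd86 and Cd83 rose by 0.85 ± 0.10 and 0.94 ± 0.08, and Il12a and Il12b, the subunits of IL-12, by 1.95 ± 0.27 and 2.78 ± 0.17; the change of Il12a, a dim gene, was 2.50 with a pseudocount of 1 and 1.20 with 64. Tnf rose by 2.22 ± 0.10, and Ido1, an enzyme of tryptophan breakdown, by 2.37 ± 0.21. Il10 rose by 1.76 ± 0.26 (adjusted p = 0.00671), from signals of 14.8 and 20.0 to 90.8 and 94; without immature replicate 1 its change was 1.62, with adjusted p = 0.0504, the highest of its alternatives (from 0.00309), and with pseudocounts of 1 and 64 it was 2.43 and 0.98. Cd80 had a change of 0.66 ± 0.22 (adjusted p = 0.105), and 0.95 with adjusted p = 0.0438 without immature replicate 2; its alternatives ranged from adjusted p = 0.0384 to 0.671. Ccr7, the receptor that guides mature DC to lymph nodes, had a change of 0.39 ± 0.12 (adjusted p = 0.0873). Itgax, Cd1d1 and the MHC class II gene H2-Ab1 had changes of -0.19 ± 0.08, 0.17 ± 0.12 and 0.08 ± 0.08, with adjusted p = 0.174, 0.410 and 0.599.

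Regulatory molecules moved in both directions. Of 23 measured, 10 rose and 3 fell; adjusted over the list alone, 12 were higher and 4 lower. Cd274, Pdcd1lg2 and Socs3 were among the rises, and Cd200r1, the receptor of CD200, fell by 1.5 ± 0.10. Camera gave regulatory molecules adjusted p = 3.91e-04, and adjusted p = 0.281 with an estimated correlation; without genes of activated T cells, 3 of 12 rose and 3 fell (adjusted p = 0.357). Of 23 survival and apoptosis genes, 11 rose and 1 fell, and 11 and 2 when adjusted over the list alone. Casp4, an inflammatory caspase, rose by 2.74 ± 0.12, Casp1 by 0.98 ± 0.09 and Bcl2l11, the gene of the pro-apoptotic protein BIM, by 1.87 ± 0.12. This list had adjusted p = 2.96e-04, and adjusted p = 0.154 with an estimated correlation; without genes of activated T cells, 10 of 22 rose and 1 fell.

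Immediate early and stress genes rose in part. Of 26 genes of the AP-1, ERK and immediate early list, 10 rose and 0 fell (2 fell without further normalization), and 12 were higher and 3 lower when adjusted over the list alone. Nr4a1, an orphan nuclear receptor, rose by 3.81 ± 0.16, Spry1, an inhibitor of ERK signalling, by 3.30 ± 0.19 and Atf3 by 2.00 ± 0.13. The list had adjusted p = 3.61e-04, and adjusted p = 0.154 with an estimated correlation; without genes of activated T cells, 8 of 22 rose. Of 18 unfolded protein response and heat shock genes, 6 rose and 0 fell, also when adjusted over the list alone; without further normalization 5 rose and 1 fell. The heat shock genes Hspa1a and Hspa1b, near-identical paralogs that probe sets may not separate, rose by 4.83 ± 0.20 and 3.52 ± 0.16, and Asns, asparagine synthetase, by 1.00 ± 0.11. This list had adjusted p = 3.10e-04, and adjusted p = 0.154 with an estimated correlation.

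Cell cycle genes fell. Of 33 measured, 27 fell and 0 rose, with a median change of -0.84, and 29 were lower when adjusted over the list alone. Mcm7, a subunit of the replicative helicase, fell by 1.32 ± 0.09 (adjusted p = 3.71e-04), Cdt1, a replication licensing factor, by 0.89 ± 0.09 and Ccnb2, a mitotic cyclin, by 0.96 ± 0.12. For the cell cycle camera gave adjusted p = 1.78e-13, and adjusted p = 0.154 with an estimated correlation. Of 18 cholesterol and fatty acid synthesis genes, 12 fell and 1 rose, with a median of -0.79; adjusted over the list alone, 16 were lower and 1 higher. They fell in the arrays in which 14 of 22 T and NKT cell markers rose. Fdft1 and Sqle, consecutive enzymes of sterol synthesis, fell by 1.55 ± 0.12 and 1.39 ± 0.13, Hmgcs1, which makes HMG-CoA, by 1.24 ± 0.11 and Scd2, a fatty acid desaturase, by 1.02 ± 0.09. The list had adjusted p = 1.92e-07, and adjusted p = 0.154 with an estimated correlation.

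**Figure D3:**
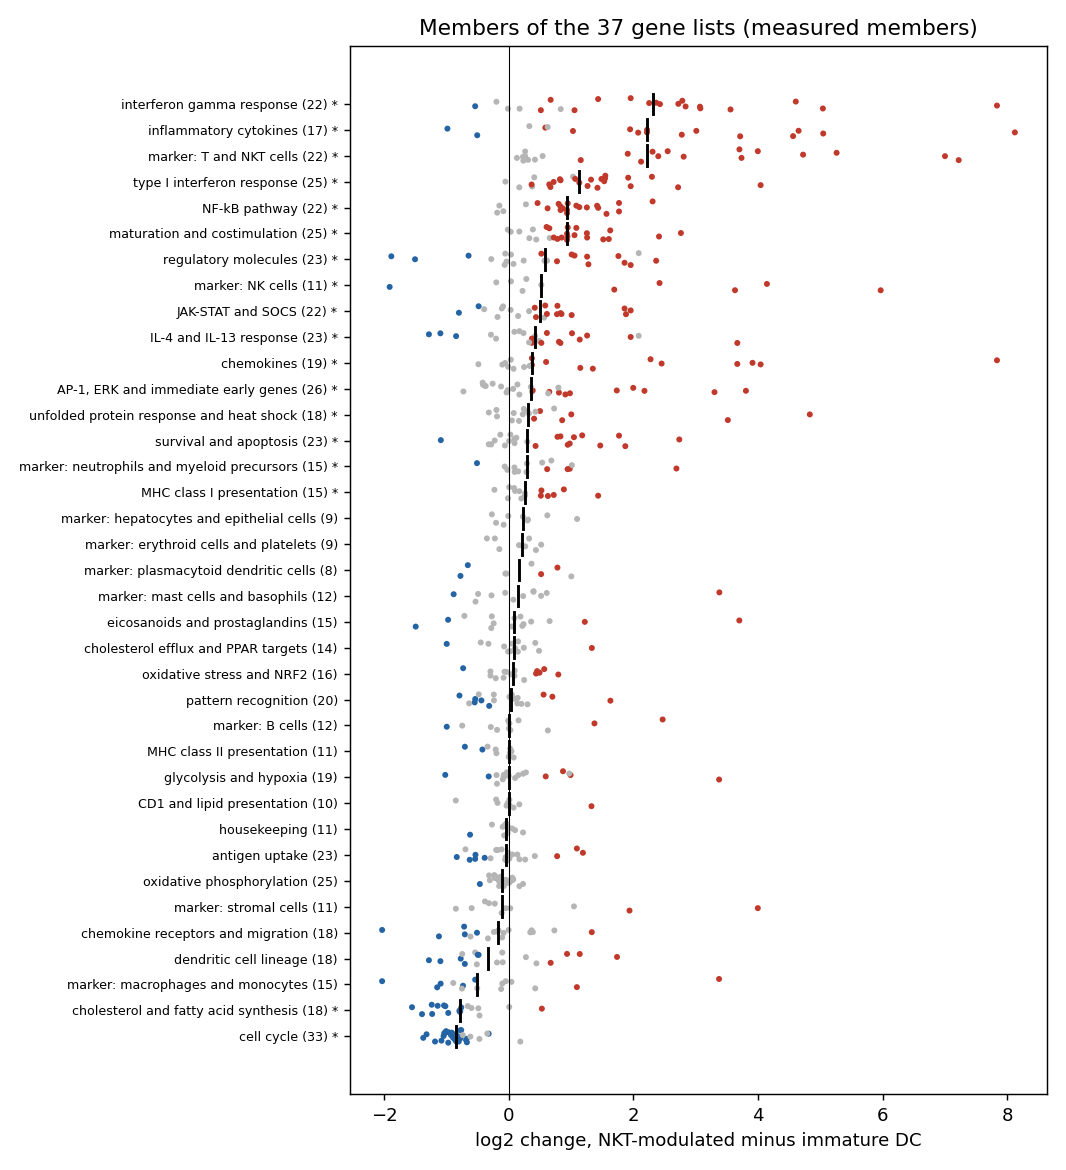
Log2 change (NKT-modulated minus immature DC, horizontal axis) of the measured members of the 37 gene lists, 1 row per list with the number of members in parentheses; points are genes, red called higher, blue called lower, grey neither, black bars are list medians, and an asterisk marks the 18 lists past the threshold with camera at the preset correlation. The medians ran from -0.84 for the cell cycle to 2.31 for the interferon gamma response.

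The 12 largest falls were of varied kinds. After Rgs18 came B3gnt8, a glycosyltransferase, with a fall of 2.62 ± 0.27, Mycl, a transcription factor of the MYC family, with -2.40 ± 0.35 and Cep131, a centrosomal protein, with -2.31 ± 0.31. Itln1 fell by 2.26 ± 0.27 and Dlgap5, a mitotic spindle protein, by 2.23 ± 0.25. St6galnac2 and Fut7, which add sialic acid and fucose to glycans, fell by 2.21 ± 0.22 and 2.17 ± 0.25, Il16 fell by 2.20 ± 0.22, and Cd34, a marker of haematopoietic progenitors, fell by 2.16 ± 0.20. Rflnb and Flvcr2 fell by 2.11 ± 0.42 and 2.10 ± 0.34. Without immature replicate 1 these 2 genes had adjusted p = 0.0538 and adjusted p = 0.0636, without immature replicate 2 Rflnb had adjusted p = 0.110, and without the intensity trend 0.0766.

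Several lists held opposite changes and did not pass. Of 18 dendritic cell lineage genes, 4 rose and 6 fell (adjusted p = 0.570; adjusted over the list alone, 5 and 8); Batf3, a factor of conventional DC, rose by 1.74 ± 0.09, and Bcl6 fell by 1.28 ± 0.11. Of 18 genes of chemokine receptors and migration, 1 rose and 5 fell (adjusted p = 0.239; adjusted over the list alone, 2 and 6); the monocyte chemokine receptors Ccr2 and Ccr1 fell by 2.03 ± 0.21 and 0.72 ± 0.09, and Ccr1 had adjusted p = 0.0553 without the intensity trend. Of 23 antigen uptake genes, 3 rose and 5 fell (adjusted p = 0.824; adjusted over the list alone, 3 and 7), with Ly75, the receptor DEC-205, rising by 1.19 ± 0.15 and Clec4a2 falling by 0.83 ± 0.08. Of 20 pattern recognition genes, 3 rose and 5 fell (adjusted p = 0.988; adjusted over the list alone, 4 and 6), with a median of 0.03 and a mean of -0.02. The balance of these calls turned with the scaling: 4 rose and 2 fell after cyclic loess, and 1 rose and 4 fell without further normalization. Clec4e rose by 1.63 ± 0.08. Of 15 eicosanoid and prostaglandin genes, 2 rose and 2 fell (adjusted p = 0.680; the counts adjusted over the list alone were the same). Ptgs2, the inducible cyclooxygenase, rose by 3.70 ± 0.21 and Ptger2 by 1.22 ± 0.17, while Alox5ap and Lta4h, which act in leukotriene synthesis, fell by 0.97 ± 0.08 and 1.49 ± 0.12.

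The other presentation and metabolic lists did not pass. Of 11 MHC class II presentation genes, 0 rose and 2 fell (adjusted p = 0.480; the counts adjusted over the list alone were the same), with H2-DMa, a peptide-exchange factor, falling by 0.70 ± 0.08. The other fall, H2-DMb2, lost its call without immature replicate 1 (adjusted p = 0.105), NKT-modulated replicate 1 (0.155) or NKT-modulated replicate 2 (0.115). Of 10 CD1 and lipid presentation genes, 1 was higher (adjusted p = 0.756; 1 adjusted over the list alone), with a median of -0.004 and a mean of 0.03. The gene was Cd1d2, a CD1d paralog, at 1.33 ± 0.24; without any 1 of the 4 arrays its adjusted p lay between 0.0502 and 0.0885. Of 19 glycolysis and hypoxia genes, 4 rose and 2 fell (adjusted p = 0.184; adjusted over the list alone, 5 and 2), with a median of -0.002 and a mean of 0.29; Egln3, an oxygen-sensing hydroxylase, rose by 3.38 ± 0.18 and Pfkp by 0.87 ± 0.08. Of 25 oxidative phosphorylation genes, 0 rose and 1 fell (adjusted p = 0.357; the counts adjusted over the list alone were the same), with Sdhd, a subunit of succinate dehydrogenase, falling by 0.46 ± 0.09; without immature replicate 1, NKT-modulated replicate 1 or NKT-modulated replicate 2 its adjusted p was 0.0724, 0.0955 and 0.0971. Of 16 oxidative stress and NRF2 genes, 5 rose and 1 fell (adjusted p = 0.285; the counts adjusted over the list alone were the same; without further normalization 3 and 1), with Sod2, a mitochondrial superoxide dismutase, rising by 0.80 ± 0.09 and Cat, catalase, falling by 0.73 ± 0.08. Of 14 genes of cholesterol efflux and PPAR targets, 1 rose and 1 fell (adjusted p = 0.58; the counts adjusted over the list alone were the same), with Fabp4 rising by 1.33 ± 0.30 and Angptl4 falling by 1.0 ± 0.24. The call of Angptl4 was lost without any 1 of the 4 arrays (adjusted p from 0.0890 to 0.222) and with the mean over its probe sets (adjusted p = 0.445), and that of Fabp4 without NKT-modulated replicate 1 (adjusted p = 0.132) or 2 (adjusted p = 0.0885). Of 11 housekeeping genes, 0 rose and 1 fell (adjusted p = 0.824; the counts adjusted over the list alone were the same); Gusb fell by 0.62 ± 0.08 (adjusted p = 0.0640 without the intensity trend), and B2m had a change of 0.10 ± 0.08.

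Markers of other cell types gave a mixed picture. Of 15 markers of neutrophils and myeloid precursors, 4 rose and 1 fell (also when adjusted over the list alone), and without further normalization 1 rose and 1 fell. Cxcr2, a chemokine receptor, rose by 2.69 ± 0.17. Ngp and S100a8 had adjusted p = 0.0553 and 0.159 without further normalization, and both lost their calls without immature replicate 1 (adjusted p = 0.0639 and 0.115) and without NKT-modulated replicate 1 (adjusted p = 0.115 and 0.160). The neutrophil list had adjusted p = 0.00258, and adjusted p = 0.199 with an estimated correlation. Of 15 macrophage and monocyte markers, 2 rose and 5 fell (adjusted p = 0.239; adjusted over the list alone, 2 and 6), with Vcam1 rising by 3.37 ± 0.15 and Ccr2 falling. Of 12 mast cell and basophil markers, 1 rose and 1 fell (adjusted p = 0.286; the counts adjusted over the list alone were the same); Hdc, histidine decarboxylase, rose by 3.38 ± 0.22. The fall was Kit, which lost its call without immature replicate 1 (adjusted p = 0.0757), immature replicate 2 (0.0876) or NKT-modulated replicate 2 (0.0575). Of 12 B cell markers, 2 rose and 1 fell (adjusted p = 0.623; the counts adjusted over the list alone were the same), with Cd79b rising by 2.47 ± 0.23. The other rise, Pou2af1, lost its call without immature replicate 1 (adjusted p = 0.175), NKT-modulated replicate 1 (0.101) or NKT-modulated replicate 2 (0.135), and the fall, Ighm, had a change of -0.02 (adjusted p = 0.979) with the mean over its probe sets. Of 8 plasmacytoid DC markers, 2 rose and 2 fell (adjusted p = 0.58; adjusted over the list alone, 3 and 2); without further normalization 0 rose, and the 4 genes, Tcf4, Bcl11a, Spib and Pacsin1, lost their calls without immature replicate 1 (adjusted p = 0.0944, 0.127, 0.0635 and 0.151). Of 11 stromal markers, 2 rose and 0 fell (adjusted p = 0.638; adjusted over the list alone, 3 and 2), with a median of -0.11 and a mean of 0.41; the rises were Thy1, also a T cell marker, by 4.0 ± 0.18 and Lum by 1.94 ± 0.26. None of 9 erythroid and platelet markers (adjusted p = 0.239) and none of 9 hepatocyte and epithelial markers (adjusted p = 0.446) changed in limma, with counts of 0 adjusted over the list alone and 0 at an unadjusted p under 0.05; Ppbp and Cdh1, the members with the smallest p, had changes of -0.35 ± 0.16 and -0.20 ± 0.09.

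Further calls within the list counts were lost without 1 array. Without NKT-modulated replicate 1, the pattern recognition genes Tlr1, Tlr4 and Cd14 had adjusted p = 0.149, 0.174 and 0.0639, and Mmp8, of the migration and neutrophil lists, had adjusted p = 0.0764. Without NKT-modulated replicate 2, Srxn1 and Mt2 of oxidative stress had adjusted p = 0.0979 and 0.060, Hk2 of glycolysis 0.0819, Mmp14 of migration 0.0518 and Tapbp of MHC class I 0.0541. The sign of the median changed with the scaling between arrays in 9 lists that did not pass: plasmacytoid DC, antigen uptake, B cells, glycolysis, pattern recognition, housekeeping, MHC class II, CD1 and oxidative stress. All 18 lists past the threshold with the preset correlation kept it with fry, and none of them kept it with an estimated correlation, a test that rests here on 2 residual degrees of freedom.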

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

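The setting without genes made by activated T cells was chosen after the data were seen; all others were planned. Directions were compared where the main or the alternative setting passed the threshold, and none reversed. Over 14 alternatives other than the estimated correlation and the lists without genes made by activated T cells, the 18 list calls were lost 0 times, with a highest adjusted p of 0.0230. The setting without an intensity trend is among the 14, but it enters the fits of single genes only. Its list tests repeat the main ones and could not lose a call. With an estimated correlation the adjusted p was 0.154 for maturation, inflammatory cytokines, type I interferon, interferon gamma, NF-kB, chemokines, MHC class I, cell cycle, cholesterol synthesis, survival, AP-1, heat shock, JAK-STAT and T and NKT markers, 0.281 for regulatory molecules, 0.206 for IL-4 and IL-13 response, 0.288 for NK markers and 0.199 for neutrophil markers; the residual degrees of freedom, 2, enter that test by its construction. Fry, which does not compare a list with other genes, called chemokine receptors (adjusted p = 0.0106), MHC class II (0.0461), oxidative phosphorylation (0.0316), mast cell (0.00520) and stromal markers (0.0316) as well. Without genes made by activated T cells the adjusted p was 0.357 for regulatory molecules, 0.0569 for JAK-STAT and 0.135 for NK markers; those lists were shorter by construction. The counts of probe sets higher and lower and of genes higher and lower were 625, 420, 471 and 396 without an intensity trend, 197, 36, 170 and 47 at an adjusted p under 0.001, 759, 586, 490 and 438 at an unadjusted p under 0.001, and 636, 447, 408 and 301 at 2-fold or more. With an array left out, limma took the lone array of a group to vary like the other group, and the counts were 624 to 822, 446 to 625, 494 to 597 and 446 to 560; probe sets lower were 575 and 579 without immature replicates 1 and 2, and probe sets higher and lower were 624 and 446 without NKT-modulated replicate 1 and 694 and 625 without NKT-modulated replicate 2. Of the genes called then, 1026, 1030, 889 and 1006 were among the 1825 called with all arrays, and 19, 10, 16 and 18 of 136 named calls were lost without immature replicates 1 and 2 and NKT-modulated replicates 1 and 2; fewer arrays explain fewer calls by construction. Il10 ranged from 1.62 to 1.86 and Cd80 from 0.36 to 0.95 in these fits, with adjusted p = 0.0504 for Il10 without immature replicate 1 and 0.0438 for Cd80 without immature replicate 2; over all alternatives the adjusted p ranged from 0.00309 to 0.0504 and from 0.0384 to 0.671. Without probe sets below the median signal, Cd80 (0.66) and Ccr7 (0.39) passed in limma, with adjusted p = 0.0384 and 0.0355. In that setting fewer probe sets were tested and the variance trend was refitted. Which of these gave the calls was not tested. The adjusted p of Ccr7 reached 0.335 elsewhere. With the mean over probe sets, Mcm3 and Tap1 lost their calls (adjusted p = 0.446 and 0.328); the cause was not tested. Over all alternatives, 1798 comparisons of named genes were unchanged, 100 lost a call and 10 gained one. Without further normalization and after cyclic loess, 1546 and 1629 of the 1825 called genes remained called, with 0 in the opposite direction. Signal over background limits dim genes: 17.1% to 18.3% of probe sets had a signal below 16.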

Other observations

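The lists of T cell receptor and CD3 genes and of genes activated T cells make, and the tests that use them or that compare cell cycle with DC genes, were chosen after the results were seen, as were the genes named in the first 2 paragraphs here; the second T lineage list was written before its values were seen.

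Some genes picked by their values, with no list or test of a group behind them, act in fatty acid and sterol synthesis. Fads1 and Fads2, the desaturases of polyunsaturated fatty acid synthesis, fell by 2.04 ± 0.12 and 1.56 ± 0.16 (adjusted p = 2.33e-04 and 0.00171). The elongase genes Elovl5, Elovl6 and Elovl7 fell by 1.45 ± 0.11, 1.45 ± 0.14 and 1.36 ± 0.22, and Msmo1, a sterol oxidase, fell by 1.51 ± 0.10. Other members of these families varied: Fads3 fell by 0.58 ± 0.15, Elovl4 rose by 0.96 ± 0.25, and Elovl1, Elovl2 and Elovl3 had changes of -0.25 ± 0.08, -0.14 ± 0.25 and -0.11 ± 0.27 that did not pass. Signals of Elovl5 were 7340 and 7772 in immature DC and 2564 and 2999 in NKT-modulated DC.

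Single genes of lymphocytes and others were picked in the same way. Cxcr6, a chemokine receptor of NKT and effector T cells, rose by 5.88 ± 0.16, and Tbx21, the T-bet gene, by 3.90 ± 0.27. Il2, Il9 and Il21 rose by 3.80 ± 0.32, 3.26 ± 0.26 and 3.33 ± 0.28. The NK receptor genes Klrb1b and Klrb1f fell by 1.64 ± 0.17 and 1.67 ± 0.25, and Itgae, the CD103 integrin of some DC and T cells, fell by 1.80 ± 0.11. Penk, the enkephalin precursor, rose by 5.91 ± 0.17.

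T lineage transcripts and T cell cytokines were higher in the NKT-modulated arrays. Expression of cytokine genes by DC alone leaves unexplained the T cell receptor and CD3 genes, whose median change was 3.72 (6 of 6 higher, 2.81 to 5.70). These genes are part of the pattern itself, so they do not tell which cells made the cytokine transcripts. The choice among the 3 scalings does not account for the rise, since the marker list's median was at least 2.11 under each. The quartiles of the arrays differed by at most 0.27, so these scalings had little room to move a median. Scaling done before the values were submitted was not varied. RNA of NKT cells in these samples stays open as a candidate explanation. In the second T lineage list 41.7% (5 of 12) were higher and 0 lower. This share lies between the bounds set in advance (over 50% if so, under 25% if not). Over all genes, 824 of 12393 were higher. The rise of the T cell receptor and CD3 genes goes with this explanation, though these genes were chosen after the results were seen. Signals in the immature arrays were 19.1 and 15.4 for Cd3g, 82.26 and 97.75 for Thy1 and 36.7 and 26.7 for Trbv1. In the NKT-modulated arrays they were 1401 and 1046, 1883 and 1309, and 2733 and 2147. Each probe set, compared with itself, shows more of these transcripts in the NKT-modulated arrays. Their levels do not tell how much RNA came from T or NKT cells, since different probe sets are not comparable. All 22 marker genes had a positive change. Of these, 8 did not pass, among them Cd2, Cd5 and Cd6 (named after their values were seen). A CD11c selection, as the design text names, is meant to remove cells without CD11c. How far it did so was not measured here. A signal over 100 was seen in both immature arrays for 3 of 22 marker genes and 3 of 12 second-list genes. In both NKT-modulated arrays it was seen for 14 and 6 of them. NKT modulation as a biological change of the DC was not separately tested for these genes.

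Cell cycle genes were lower in the NKT-modulated arrays. Dilution of DC RNA by other RNA, as the only cause, is argued against by their median change. It was lower by 0.74 than that of 41 DC lineage and antigen uptake genes (difference -0.737, one-sided permutation p = 1e-04, the smallest that 10000 relabellings can give). Genes are not independent replicates. The median was -0.337 for the DC lineage list alone and -0.049 for antigen uptake. These reference genes changed themselves: 4 rose and 6 fell in the first list, and 3 rose and 5 fell in the other. They therefore do not measure dilution cleanly, and a part of the fall through dilution is not excluded. The choice among the 3 scalings does not account for the fall, since the median was at most -0.77 under each. These scalings had little room to move it, as the quartiles of the arrays differed by at most 0.27. Noise of dim probe sets is argued against by a median of -0.84 among 26 cell cycle genes above the median signal, of which 23 were lower. Modulation by NKT cells, the difference the design names, stays open as a biological hypothesis and was not tested apart from the groups. The dilution test covered the cell cycle list and no other falling list.

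Inflammatory cytokine genes were higher in the NKT-modulated arrays. RNA of NKT cells alone is argued against by the median change of 1.95 that remained without genes made by activated T cells (8 of 11 higher, 1 lower). The choice among the 3 scalings does not account for the rise, since the full list's median was at least 2.10 under each. These scalings had little room to move it. Modulation of the DC by NKT cells, the difference the design names, stays open as a hypothesis and was not tested apart from the groups. The genes left out were chosen from general knowledge, and RNA of NKT cells may still add to single genes.

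The 4 arrays can be split into 2 and 2 in 3 ways. The real split gave 2501 limma calls and the highest other split 0, with 5701 probe sets at an unadjusted p under 0.05 in the real split and 592 and 415 in the others. With 3 splits no share under 0.05 can be reached. In the other splits each side held an immature and an NKT-modulated array. The difference between the real groups then enters the residual variance and lowers the calls, so these counts are no null reference for the real split.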
